A study of Marchantia polymorpha with 6 samples.

How the data were processed

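The libraries were made from poly(A) RNA of thalli with a directional kit, per the labels' protocols, and the submitters' processing notes list Trim Galore and STAR without a version. How reads were counted is not given in the sources used here. The 2 deposited files were GTF annotations, and the values used are genome positions in bp, the first and the last base of each feature, counted from 1. The score column, deposited in both files, held a dot in every row, so no identity to a family consensus was read from it. The authors' gene annotation held 276543 rows, of which 145465 were exons and 131078 were coding parts. The authors' element annotation names EDTA, a pipeline that annotates transposable elements, as the source of every row; its version and settings are not given in the sources used here. Both files were named for the Tak-1 assembly MpTak1 v5.1 revision 2. No column held a value of a library, so the 3 wild-type and 3 Mpmet-3 libraries entered no test, and the planned comparisons of gene and element expression and of Gypsy against Copia identity were not made.

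A gene was taken as the span of its exon rows, its exons as the union over transcripts and its introns as the rest of the span. A base in any exon counted as exon, a base in an intron and in no exon as intron, and every other base as outside genes. The length of a sequence was its last feature end over both files, since no sequence lengths were used. Overlapping copies were merged before bp were counted, within a superfamily or over all elements. Copies were called structure-based where their identifier began with TE_struc or LTRRT and homology-based where it began with TE_homo, a reading of the identifiers that gave 1325 and 87937 copies. A strand was missing for 847 copies. Superfamily codes were read by the usual three-letter scheme of plant element classification.

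Placement was tested with 1000 circular shifts of all elements within each sequence, which keep the clustering of elements, and 2-sided empirical p-values whose smallest value is 0.000999. A gene counted as having an element upstream when at least 1 bp of it lay in the 1000 bp before its start. Window counts used 100 kb windows on 9 chromosomes and the same kind of shift, moved by whole windows. Each gene was counted in the window that held its midpoint. The length of intronic copies was also set against 1000 such shifts. Differences paired by chromosome were tested with exact 2-sided sign-flip permutation over 9 chromosomes. V was set against the 8 autosomes with an exact 1-sided permutation test, on the side where V lay. No side was fixed beforehand, so these p-values are smaller than 2-sided ones would be. Lists were compared with the other coding genes by Fisher's exact test. Adjusted p-values follow Benjamini and Hochberg within each family, and the threshold was 0.05. Chromosomes and shifts describe 1 annotated genome, so no p-value here speaks of variation between plants.

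The tests of placement were tried on simulated elements on 3 chromosomes with 40 trials of 200 shifts and 6000 elements of 300 bp. With random placement, the exon test made 0 false calls in the 40 trials, the upstream test 2 and the window test 3. The simulated elements were placed independently of each other, without the clustering or the range of lengths of the real ones. False calls on clustered elements were therefore not measured. When 50% of the exonic elements were kept, the planted ratio of 0.578 was recovered as 0.592 ± 0.0205 and called by the exon test in 40 of 40 trials, and the window test called the depletion in 35 of 40. Detection by the upstream test was not simulated.

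Gene symbols came from a table for the female assembly MpTak2 v7.1, whose locus tags match none of the identifiers exactly. Tags with the same number after the prefix were paired for 17369 genes; of these pairs 16228 (93.4%) had gene lengths within 5% of each other, against 5.17% when each gene was paired with the next number. Only pairs within 5% were used, and 2864 genes received a symbol. Symbols therefore rest on number and length, not on sequence, and genes of V have none.

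Before the data were examined, the genes to be named were fixed as Mp4g09580, the 10 genes with most exonic and the 10 with most intronic element bp, and the matched members of the lists. The lists were DNA methylation (8 of 14 symbols matched), small RNA (9 of 12), histone methylation (2 of 4) and a list headed male germ line (5 of 7). The last was drawn up for another cell type that a male plant could hold. Whether its members are particular to that cell type, or to males, was not examined. In the DNA methylation list 1 further symbol and in the histone list 1 was left out because its lengths differed. The alternatives were other sets of genes, transcripts and elements, other upstream distances and window sizes, uniform placement, and the autosomes alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.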

Results

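The series concerned the liverwort Marchantia polymorpha and the effect of losing MpMET, the liverwort counterpart of the plant enzyme that maintains methylation at CG sites, on the expression of genes and transposable elements. The 6 RNA-seq libraries came from thalli, the flat haploid plant body, at 14 days. There were 3 libraries of the wild-type male line Tak-1 and 3 of the Mpmet-3 mutant. Both deposited files were genome annotations of Tak-1, with no value for any library, so the expression of genes and elements in Mpmet-3 against the wild type was not analysed here and the depth per library is unknown. The files define the genes and elements whose expression the series set out to compare, and the comparisons made here describe how these lie in the genome. None of them measures an effect of the mutation. Positions refer to MpTak1 v5.1 revision 2.

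The gene annotation held 19441 genes with 24807 transcripts. Of these genes 18288 had a coding sequence, with a median span of 3034.5 bp, and 1153 did not, with a median span of 82 bp. At least 2 transcripts were annotated for 3294 genes (16.9%). The element annotation held 89262 copies, from 50 to 21573 bp long with a median of 348 bp. They carried 1260 family labels, some of which name only a part of an element, and 17 labels of class and superfamily. These 17 are called superfamilies below, though some of them name no known superfamily. The annotations reached over 8 autosomes, the male sex chromosome V and 414 unplaced sequences, 218 Mb in all when each sequence was measured to its last feature.

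Transposable elements covered 56.4 Mb, or 25.8% of the sequence, and LTR retrotransposons, which move through an RNA copy, made up most of it. Gypsy elements alone covered 28.9 Mb with 27531 copies, 51.3% of all element bp. LTR elements placed in no superfamily held 17.1% and Copia elements, the other large LTR superfamily, 7.92% with 7117 copies. Elements of unknown class held 12.7%. Among DNA transposons the Mutator group (DTM) came first with 6.55% of element bp, followed by CACTA (DTC) with 3.86%, hAT (DTA) with 1.81% and Tc1/Mariner (DTT) with 1.29%. Short inverted-repeat elements related to Mutator (MITE/DTM) and to hAT (MITE/DTA) held 0.669% and 0.476%. These shares count a base once within a superfamily, so bases claimed by several superfamilies make the superfamily total 58.9 Mb.

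Copies found by their structure, as read from their identifiers, were 1.48% of all copies and 8.35% of element bp. Their median length was 6062 bp for the 433 Gypsy copies, 6309 bp for Copia and 2098 bp for DTM. Over all copies the medians were 569, 287 and 227.5 bp. The Gypsy and Copia lengths are not in the same unit. Copies found by homology were matched to library entries that hold the terminal repeat or the inner part of an LTR element separately. A single LTR element can thus be listed as several copies. This reason does not cover DTM. How complete the copies are was not measured. On V the structure-based share of element bp was 2.84%, below the range of 7.93% to 11.5% on the autosomes. Among structure-based elements alone, Gypsy held 62.2% of element bp.

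Chromosome V carried few genes and many elements. It held 19.4 genes per Mb, against 91.6 ± 2.41 (SD, n = 8) on the autosomes, and elements covered 61.7% of it, against 23.9% ± 2.68 (SD, n = 8). With coding genes alone the values were 12.3 per Mb on V and 86.9 ± 2.48 (SD, n = 8) on the autosomes, a ratio of 0.142 in place of 0.211. The autosomes ranged from 19.3% element cover on chromosome 1 to 28.0% on chromosome 4. Gypsy elements covered 33.2% of V and 12.2% ± 1.67 (SD, n = 8) of the autosomes. DTC covered 2.84% against 0.928% ± 0.111 (SD, n = 8) and DTT 1.29% against 0.289% ± 0.0613 (SD, n = 8). The hAT elements went the other way, with 0.235% of V and 0.477% ± 0.0807 (SD, n = 8) of the autosomes. In each of these measures V lay outside the range of all 8 autosomes, for which the exact 1-sided permutation p is 0.111, the smallest that 9 chromosomes allow, so no difference of V could pass 0.05. Only for DTM did V lie within the autosomal range among the 10 superfamilies with most covered bp (1.96% against 1.66% ± 0.182, n = 8; exact permutation p = 0.222). The unplaced sequences held 2.66 Mb with 190 genes, and elements covered 80.9% of them.

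**Figure D1:**
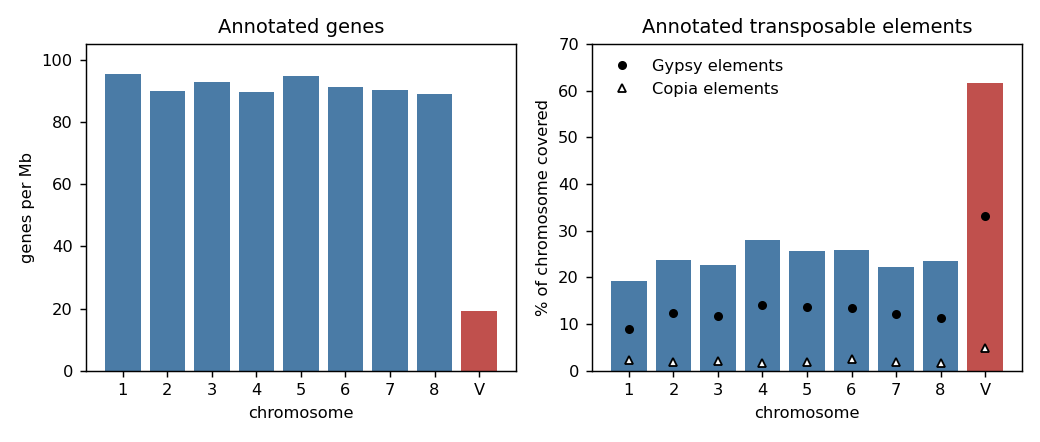
Left, annotated genes per Mb of each chromosome; right, percent of each chromosome covered by elements (bars), by Gypsy elements (filled circles) and by Copia elements (open triangles), with V in red. V held 19.4 genes per Mb and 61.7% element cover, and the autosomes ranged from 19.3% to 28.0% cover; each bar is the value of a whole chromosome, so there are no error bars.

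Elements lay mostly outside genes. Exons held 3.09% of element bp, against 18.3% ± 0.225 (SD of 1000 circular shifts) when the elements were shifted along each sequence, a ratio of 0.169. Introns held 4.04% against 14.2% ± 0.241, a ratio of 0.284, and the space outside genes held 92.9% against 67.5% ± 0.409, a ratio of 1.38. The p was 0.000999 in each case, the smallest that 1000 shifts can give. All 10 superfamilies tested held less than under the shifts in exons and in introns and more outside genes (adjusted permutation p = 0.000999 over 30 tests). The size of the exon deficit differed widely. Gypsy had an exon ratio of 0.0134 and Copia of 0.0570, while DTM had 0.375, DTC 0.382 and elements of unknown class 0.624. Differences between superfamilies were not tested. The intron ratio rested in part on V: on the autosomes alone it was 0.159, and the exon ratio was 0.153.

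Of the 19441 genes, 3049 (15.7%) had at least 1 bp of an element within 1 kb upstream of their start, against 35.1% ± 0.379 (SD of 1000 shifts), a ratio of 0.447 (permutation p = 0.000999, the smallest possible). Of the 10 superfamilies, 8 were found upstream of fewer genes than under the shifts, 1 upstream of more, and 1 did not pass the test. Gypsy was upstream of 286 genes, at a ratio of 0.0871, and Copia of 155 genes, at 0.202. MITE/DTA was the superfamily found more often, upstream of 206 genes (1.06%) against 0.620% ± 0.0556, a ratio of 1.71 (adjusted permutation p = 0.00111). For its larger relatives, the hAT elements, the ratio was 0.873 (adjusted permutation p = 0.0629). In the 1 kb downstream of genes, examined after the upstream values were seen, 7 superfamilies were found at fewer genes than under the shifts, 1 at more and 2 did not pass. The superfamily at more genes was again MITE/DTA, with 150 genes and a ratio of 1.25 (adjusted permutation p = 0.00999). The shifts also place elements inside genes, where MITE/DTA was scarce: outside genes lay 90.4% of its bp against 66.8%, a ratio of 1.35. The downstream ratio, though it counts genes and not bp, was no higher, so it shows no excess beyond absence from genes. The upstream ratio of MITE/DTA was not tested against this. DTM and MITE/DTM had downstream ratios of 1.03 and 1.06 (adjusted permutation p = 0.312 and 0.434). Their bp outside genes had ratios of 1.31 and 1.35, and that of the hAT elements 1.42. A flank ratio near 1 thus does not mean that they were as common there as elsewhere outside genes, which was not tested. Upstream and downstream values were not tested against each other.

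**Figure D2:**
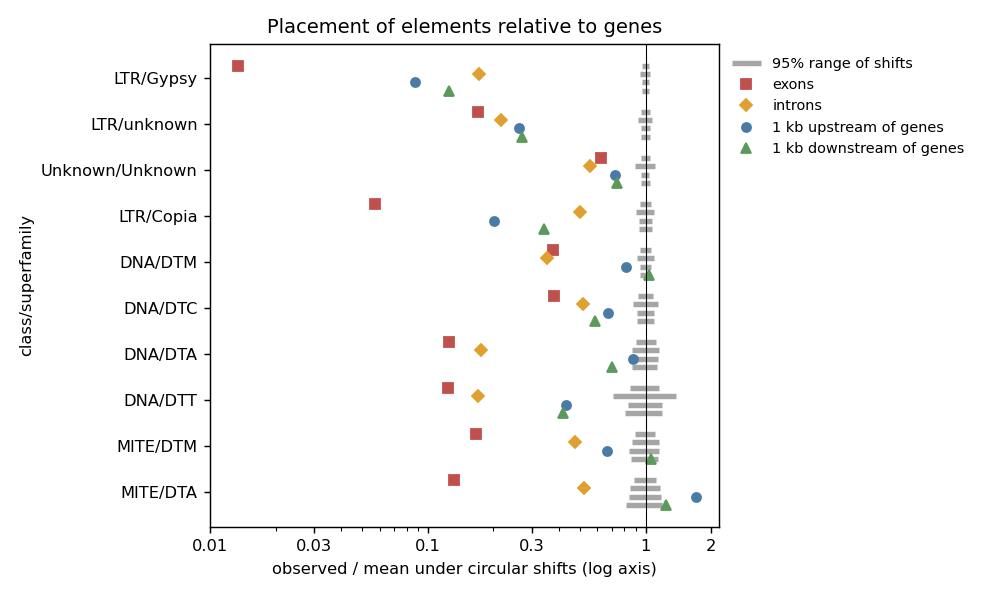
For each of the 10 superfamilies with most covered bp, the observed value divided by the mean of 1000 circular shifts (log axis), as share of element bp in exons and introns and as share of genes with an element within 1 kb upstream or downstream; grey bars give the 95% range of the shifts. Gypsy lies farthest left in exons (0.0134), and MITE/DTA lies right of its grey bar upstream (1.71) and downstream (1.25).

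Gene-rich windows held fewer elements. Over 2153 windows of 100 kb, the number of genes and the element cover had a Pearson r of −0.666 and a Spearman rho of −0.620 (permutation p = 0.000999 for both, the smallest that 1000 shifts can give; mean r under the shifts −0.120). Windows are not independent replicates, which is why whole chromosomes were shifted. The result is not separate from the scarcity of elements inside genes, which by itself lowers the cover of windows with many genes. In the simulation, loss of exonic elements alone was called by the window test in 35 of 40 trials. Whether the correlation goes beyond this scarcity was not tested. Within each autosome r lay between −0.710 (chromosome 4) and −0.421 (chromosome 1), with an adjusted p of 0.00112 in each of the 8. On V, with 75 windows, r was −0.0850 (permutation p = 0.535) and rho −0.356 (permutation p = 0.00999). Shifts moved by whole windows, so a single chromosome had fewer distinct shifts than windows, and the 1000 draws repeated them. The p-values within single chromosomes are therefore finer than their distinct shifts allow, most of all on V. By Dixon's criterion for 9 values V stood apart from the autosomes in r, with a gap of 0.538 of the range, but not in rho, with a gap of 0.468. Each gene was counted at its midpoint, so a window inside a long gene could count no gene. The introns of the 13 V coding genes over 50 kb made up 33.7% of V, and no autosome had a coding gene of that length. Whether this weakened r on V was not tested.

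The lengths of copies inside introns were those that shifted placement gives. The median length of the 3667 copies lying wholly within an intron was 225 ± 39.3 bp (mean of chromosome medians ± SD, n = 9), against 348 ± 21.0 bp for the 80974 copies outside genes. The difference was −123 ± 46.5 bp (SD, n = 9), with shorter intronic copies on 9 of 9 chromosomes (exact 2-sided sign-flip permutation p = 0.00391, the smallest possible). A copy counted here cannot be longer than its intron, so this test is set in part by the selection. When the elements were shifted along each chromosome and selected in the same way, a comparison added after the values were seen, the mean difference was −124 ± 5.20 bp (SD of 1000 shifts), and the observed difference did not depart from it (permutation p = 0.863). None of the 9 chromosomes departed from its own shifts after adjustment (smallest adjusted permutation p = 0.153, chromosome 6; 1 of 9 had an unadjusted p under 0.05). On V, which held 2109 of the intronic copies, the observed difference was −10 bp and that under the shifts −13.0 ± 37.0 bp. Among elements of at least 200 bp alone the mean observed difference was −216 ± 71.5 bp (SD, n = 9), which was not set against shifts.

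Some annotated genes consisted largely of sequence annotated as elements. This matters for any count of reads, since a read from such sequence belongs to both annotations. Of the coding genes, 2081 (11.4%) had at least 1 bp of element in an exon and 620 (3.39%) had at least 50% of their exonic bp in elements. Of the genes without a coding sequence, 348 (30.2%) had at least 1 bp and 340 (29.5%) at least 50%. The latter share leaned on V and the unplaced sequences. Of the 340 genes, 129 lay on unplaced sequences, which held 190 genes of any kind. A further 49 lay on V, where 93 of 146 genes were coding. Elements of unknown class covered 34.7% of the exonic bp of those 620 coding genes, LTR elements of no superfamily 21.9% and DTM 13.0%. In the 340 genes without a coding sequence, elements of unknown class covered 77.7%. The unknown class names no kind of element, and 0 of its copies were structure-based. Whether these copies are transposable elements or other repeated sequence was not examined. On V, 37 of 93 coding genes (39.8%) had element sequence in an exon. In all, 4621 copies touched an exon. Of the 4356 with a stated strand, 1939 (44.5%) lay on the same strand as the exon. For these, counting by annotated strand in a directional library, as prepared here, could not separate the element from the gene. Whether a stated strand is the direction of transcription was not examined.

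The 10 genes with most exonic element bp were all annotated as coding. Mp2g05030 (chromosome 2, 5230770 to 5244295, minus strand) came first with 9815 of 11451 exonic bp in elements (85.7%). Mp3g07970 (chromosome 3, 7677588 to 7684990, plus strand) was a single exon of 7403 bp lying wholly in elements. Close to each other on chromosome 6, Mp6g16340 and Mp6g16350, each had 20 merged exons, with 5891 and 5353 exonic bp in elements (94.3% and 93.7%). The other genes of this group were Mp4g13500, MpVg01223, Mp8g15140, Mp8g14510, Mp7g12460 and Mp1g08755, each with 3 to 5 merged exons and 94.9% to 99.5% of the exonic bp in elements.

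The 10 genes with most intronic element bp all lay on V, and their exons held few element bp or none. MpVg00525 (V, 2676294 to 3097587, minus strand) had 3240 bp of exon in a span of 421 kb, and 248 kb of its 418 kb of intron (59.3%) was element sequence. MpVg00615 (V, 3464430 to 3966228, plus strand) spanned 502 kb with 3471 bp of exon and 241 kb of intronic elements, and MpVg01095 (V, 5471720 to 5958331, plus strand) spanned 487 kb with 227 kb. MpVg00105 followed with 157 kb and MpVg00785 with 72.3 kb. MpVg00928, MpVg00045, MpVg00985, MpVg00410 and MpVg00265 had between 29.9 kb and 49.3 kb. Exonic element bp was 0 in 7 of the 10, and 594 bp (10.5%) in MpVg00785, 100 bp in MpVg00615 and 78 bp in MpVg00985.

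MpMET itself, given by locus number and gene length as Mp6g18180, was annotated on chromosome 6 from 20269397 to 20281226 on the minus strand, with 3 transcripts of 12 or 13 exons that shared a coding length of 5178 bp (1726 codons with the stop). Its introns held no element. An 82 bp copy of unknown class (20281190 to 20281271) overlapped the 5′ end of its untranslated sequence by 37 bp. Elements covered 597 of the 1000 bp upstream of the gene, including 2 copies of the DTM family TE_00001217, which began 208 and 679 bp from the start. Upstream of these came a run of LTR copies from 2648 bp on, while no element was annotated within 20 kb downstream of the gene.

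The gene file was named for a revised transcript of Mp4g09580, which lay on chromosome 4 from 10753423 to 10756656 on the plus strand. The locus, which shared its number with MpGT34.10, had 4 transcripts with the same coding length of 1566 bp (522 codons with the stop). Transcripts 1 and 3 had identical models of 2 exons. Transcripts 2 and 4 had 3 exons and began at 10753423, and differed in the intron nearest the start, which was 522 bp long in transcript 2 and 91 bp in transcript 4. What had been revised is not given in the sources used here. No element lay within the gene or in its upstream 1 kb. The nearest were a DTC copy 4614 bp upstream and a 100 bp copy of unknown class 1694 bp downstream. Identical transcript models occurred in 3 genes of the annotation, the others being Mp7g12820 and Mp8g16220, which were noticed after their models were compared.

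**Figure D3:**
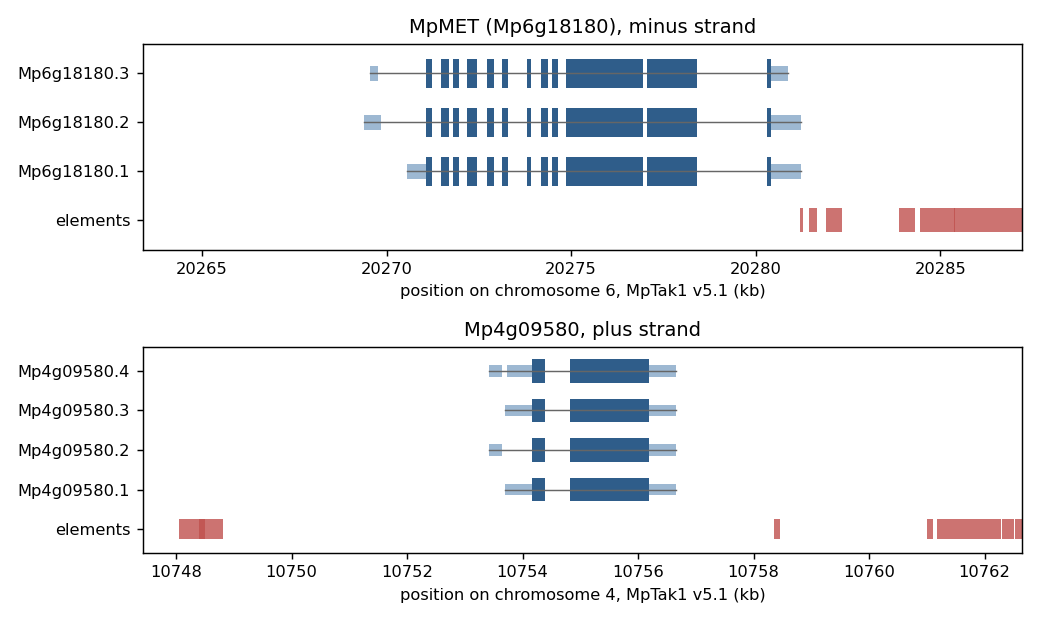
Transcript models of MpMET (top) and Mp4g09580 (bottom) over their position in kb, with coding parts as tall dark boxes, untranslated exon parts as low light boxes, introns as lines and annotated elements of either strand as red boxes. Elements begin at the 5′ end of MpMET, on the right, where 597 of the 1000 upstream bp are covered; the nearest element upstream of Mp4g09580 is 4614 bp away.

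Among genes of DNA methylation, matched to symbols by locus number and gene length, 4 of the 8 matched members (50%) had element sequence in their upstream 1 kb, against 14.4% of the other coding genes (Fisher's exact test, 2-sided p = 0.0185, adjusted p = 0.222 over 12 tests), so the excess did not pass the correction. The members were MpMET with 597 bp, the chromomethylase MpCMTb (Mp6g21040) with 437 bp, MpDNMT3b (Mp5g09290) with 135 bp and MpDRMa (Mp1g00340), a methyltransferase of the domains-rearranged type, with 43 bp. MpCMTa (Mp6g08650), MpDRMb, MpDNMT3a and the chromatin remodeller MpDDM1 had none there. In this list 1 gene had exonic element sequence (MpMET, 37 bp) and 1 had intronic element sequence (MpCMTa, 376 bp; exact p = 1 and 0.558).

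Of the small RNA genes, 9 of 12 were matched and none had an element in the upstream 1 kb, against 14.4% of other coding genes (Fisher's exact p = 0.375). Exonic element sequence was found in 1, MpAGO9 (Mp8g08610), with 332 bp. Introns of 2 members held elements, the Dicer gene MpDCL4 (Mp7g11720) with 1059 bp and MpNRPD1 (Mp3g05720), which encodes the large subunit of RNA polymerase IV, with 159 bp (exact p = 0.215). MpAGO1, MpAGO4a, MpAGO4b, MpDCL1a, MpDCL1b and MpDCL3 had none in any of the 3 places. The 2 matched histone methylation genes, MpE(z)2 and MpE(z)3 of the Polycomb group, had no element in exons, introns or the upstream 1 kb. Nor had the 5 matched members of the list headed male germ line, MpPRM, MpDUO1, MpBNB, MpRKD and MpFGMYB (exact adjusted p = 1 in each case for both lists). With so few members none of these lists could show a modest difference.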

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

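The tests of exon parts and of V introns in this part were chosen after the main placement results were seen, with their predictions written before their own values were known; the comparison without the longest genes was added after those values were seen. In 16 of 21 measures chromosome V stood apart from the 8 autosomes, by a gap that exceeded Dixon's 95% critical value for 9 values. The units are chromosomes of 1 genome, not samples. Chance gives such a gap in about 1 of 20 sets, and the measures are not independent of each other.

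V had 19.4 genes per Mb where the autosomes had 89.0 to 95.4, exon cover of 3.27% where they had 19.2% to 23.0%, and intron cover of 37.2% where they had at most 16.2%. Its element cover was 61.7%. By superfamily, V was covered by 33.2% Gypsy, 13.3% LTR elements of no superfamily, 7.75% elements of unknown class, 4.81% Copia, 2.84% DTC, 1.29% DTT and 0.359% MITE/DTM, each above the highest autosome. Structure-based copies made up 2.84% of its element bp, below the lowest autosome at 7.93%. The correlation of genes and elements over windows was −0.0850 on V, where the autosomes reached from −0.710 to −0.421. By rank correlation V did not stand apart: Spearman rho was −0.356 on V and −0.664 to −0.500 on the autosomes, a gap of 0.468 of the range, below the critical value.

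Coding genes held more intron sequence on V, with a mean of 32240 bp per gene where the autosomes had 1281 to 1776. The median was 1748 bp where the autosomes had 638 to 1141.5. These values sum all introns of a gene, and the number of introns was not compared. Elements made up 43.9% of the intron bp of V coding genes, against 2.61% to 4.90% on the autosomes. Element insertions could account for the extra length, but with element bp removed the mean on V was still 18100 bp, above the highest autosome at 1730 bp, which argues against annotated elements as the whole of it. A few very long gene models, for example joined ones, could also make the mean. The 13 V coding genes over 50 kb, 14.0% of its 93 coding genes, held 84.8% of the intron bp of V coding genes. With the same share of the longest genes left out of every chromosome, the median on V was 617 bp, within the autosomal range of 419 to 816.5, while the mean was 5701 bp, above the range of 748 to 1152. The median of 1748 bp over all 93 genes holds the models in question and decides nothing about them. These models and longer or more numerous introns of V genes therefore cannot be told apart here. Whether decayed elements escaped annotation stays open too.

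Exons held fewer elements than shifted placement gives, at a ratio of 0.169. Removal of coding sequence from the element library during annotation could produce this, but the untranslated parts of exons, which such a step would leave, had a ratio of 0.117, which argues against it as the whole cause. Short matches missed in exons could produce it too, but with elements of at least 200 bp alone the ratio was 0.161. Both tests argue against a technical cause of these 2 kinds, and masking of whole transcripts stays open. No biological explanation was tested.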

How the results depend on the processing

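No paired analysis was possible because the deposited files hold no value for any of the 6 libraries. For the same reason the alternatives for gene and element expression were not run, nor were those for Gypsy against Copia identity, which no column gives. Sequence lengths were the last feature ends already, so that alternative equals the reported value. Of the 45 other alternatives, 40 kept the direction and the side of the threshold or stayed within the spread between chromosomes. Alternatives with coding genes alone for placement, with the autosomes alone for superfamily and structure shares, and all those for MITE/DTA, V introns, strand and shifted lengths were chosen after seeing the data. Another 4 moved and 1 lost its call. The ratio of V to the autosomes in genes per Mb was 0.142 with coding genes alone in place of 0.211, since only 93 of the 146 genes of V had a coding sequence. The Gypsy share of element bp was 62.2% among structure-based elements in place of 51.3%; the cause was not tested. The ratio of V to the autosomes in mean intron bp per coding gene was 3.84 without the genes over 50 kb, in place of 21.7. It was 6.38 without the same share of the longest genes of every chromosome. The length difference of intronic copies, −123 bp, lost its call against shifted elements (permutation p = 0.863), so the sign-flip p of its 3 further alternatives says nothing of a difference beyond the selection. The upstream ratio ran from 0.338 at 500 bp to 0.607 at 2 kb, and the MITE/DTA ratio from 1.60 to 1.93. The exon ratio ran from 0.147 to 0.169, and the intron ratio from 0.159 on the autosomes alone to 0.284. The limit throughout is that these values describe 1 annotation of 1 genome.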

Other observations

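The tests of strand in this part were chosen after the placement of elements was seen. LTR elements inside introns lay more often antisense to their gene than LTR elements outside genes did to their nearest gene. Over 9 chromosomes the antisense share was 62.0% ± 6.49 (SD, n = 9) in introns and 50.5% ± 1.10 (SD, n = 9) outside genes, higher in introns on 9 of 9 chromosomes. Copia elements showed it (299 of 485 copies antisense, 61.6%, exact 95% interval 57.2% to 66.0%; mean difference 22.6 percentage points, higher on 8 of 9 chromosomes, exact sign-flip permutation adjusted p = 0.0293 over 5 tests). For Gypsy the mean difference was −2.0 percentage points (exact permutation p = 0.777) and for LTR elements of no superfamily 0.231 (exact permutation p = 0.977). For DTM it was 14.5 (adjusted exact permutation p = 0.0651). Superfamilies were not tested against each other. The interval covers counting error only and treats every copy as independent. Intronic LTR copies were grouped by gene: all 1729 lay in 218 genes, and the 1343 on V in 21 genes. For copies grouped in this way the interval is too narrow, by an amount that was not measured.

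A candidate explanation is that fewer sense insertions are kept inside introns. It predicts an antisense share above that outside genes, and the mean difference was 11.6 ± 6.61 percentage points (n = 9, exact sign-flip permutation p = 0.00391, the smallest possible; adjusted p = 0.0195). Pieces of the same insertion counted several times could give an uneven share as well, but with only the longest copy of each gene, 218 in all, the difference was still 7.34 ± 8.39 points, higher on 8 of 9 chromosomes (exact permutation p = 0.0156). V added the largest of these differences, 26.4 points, and without it the mean was 4.96 ± 4.72 points, higher on 7 of 8 autosomes (exact permutation p = 0.0312). For all LTR elements as 1 set this argues only weakly against repeated pieces as the whole cause. Each chromosome gave only 18 to 31 such copies, and of the 197 on the autosomes 55.3% were antisense. The size of the difference also fell with 1 copy per gene. Copia, the LTR superfamily that showed the difference, was not tested with 1 copy per gene, so for it repeated pieces stay open. Gene models built from transcripts that stop at sense LTRs stay open, as does the annotation of strand itself, so selection remains a hypothesis.

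Over all 1729 intronic LTR copies pooled, 54.7% were antisense, because V held 1343 of them at 52.3%. The library entry TE_00001068, the long terminal repeat of a Gypsy family singled out after its values were seen, had 4831 copies, the most of any family label. Of the 340 genes without a coding sequence that consisted mostly of sequence annotated as elements, 129 lay on unplaced sequences and 49 on V. The median length of the 340 was 158 bp.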
